A study of Mus musculus with 6 samples.

How the data were processed

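RNA was measured in the stomach corpus, the acid- and pepsinogen-secreting body of the stomach, of 6 mice on a C57BL/6 background. Per the labels, 3 mice carried the genotype Ras;APC FF and served as controls (replicates 1 to 3), and 3 carried PGC;Ras;APC FF (replicates 4 to 6), with 1 mouse per library. The labels do not spell out PGC or FF, and give no age, sex, induction scheme or time point. Per the labels' protocols, total RNA was extracted with a silica column kit including a DNase step, and libraries were prepared and sequenced at BGI. The protocols used here do not say whether the libraries were stranded.

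The deposited values are FPKM (fragments scaled to gene length and library total), which the authors computed and rounded to 2 decimals. Per the submitters' processing notes, reads were handled with STAR and featureCounts on the mouse build mm10. Versions, the gene annotation and the step from counts to FPKM are not given in the sources used here. The deposited table held 18988 rows named by gene symbol, of which 26 carried names turned into dates by a spreadsheet program. Of these, 2 names occurred on more than 1 row, and such rows were kept apart. No mitochondrially encoded gene was among the rows used here. Of all rows, 18280 had a symbol found in GENCODE mouse release M21 (GRCm38, the same assembly as mm10), from which the printed coordinates were taken by symbol. There were 75 rows with a highest FPKM of at least 0.1 whose 6 values were identical to those of another row, mainly multicopy small RNAs. Genes with near-identical copies (hemoglobin, amylase, trypsinogen and major urinary protein genes) are therefore uncertain as single genes.

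Because FPKM are not counts, no count model was used. Values were tested as log2(FPKM + 1), so log2 changes are on that scale and understate the change of low genes. Genes with an FPKM of at least 1 in at least 3 of the 6 libraries were tested (11857 genes). A linear model with the genotype as its 1 term was fitted with limma 3.58.1 in R 4.3.3 (eBayes with trend), two-sided, and p-values were adjusted by Benjamini-Hochberg over all tested genes with a threshold of 0.05. The residual degrees of freedom were 4, and 7.72 with the shared prior. An exact test of 3 against 3 mice cannot give a two-sided p under 0.1, so that calls rest on the spread shared across genes in limma.

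There were 32 gene lists, fixed before the data were examined, and 27 had at least 3 tested members. These were tested with limma camera at a preset inter-gene correlation of 0.01, which compares a list with all other tested genes, with Benjamini-Hochberg adjustment over the 27 lists. Members that passed were also counted with adjustment over all genes and adjusted over the list alone. Of all 11857 tested genes, 4196 had an unadjusted limma p under 0.05. Counts adjusted over the list alone can thus be high without setting a list apart from other genes. Camera with the correlation estimated per list, and fry, which asks whether the genes of a list move on balance in 1 direction, were run beside it. The level of a list in a library is the mean log2(FPKM + 1) of its tested members minus the mean of that value in the controls.

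The genes named were chosen by a rule set before the data were examined. It took up to 8 rises and 8 falls of largest size past the threshold, with a mean FPKM of at least 5 in the higher group and every PGC;Ras;APC FF library on 1 side of every control library. To these it added genes of the genotype labels, among them Pgc, Hras, Nras and Apc, and for each list up to 3 members past the threshold, or the most abundant tested members where fewer than 2 had passed. Genes named outside this rule are marked as chosen after their values were seen.

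The number of reads per library is unknown. Low FPKM of short RNAs came in steps of what 1 read is worth, and 47 such values from 25 genes shorter than 260 bp gave a relative depth of 1 for replicate 4, 0.976 for replicate 2, 0.974 for replicate 1, 0.936 for replicate 5, 0.833 for replicate 6 and 0.742 for replicate 3. Each of these rests on 5 to 10 values, so they are rough. Since absolute depth is unknown, no counting interval is given. Summed FPKM ranged from 664821 (replicate 6) to 804774 (replicate 3).

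The gene test was tested on simulated values for the comparison of PGC;Ras;APC FF with control, drawn over the 11857 genes. Means were the fitted ones, and variances were drawn from the fitted prior and were the same in both groups. Of 100 genes changed by 1 on the log2 scale 60% were recovered, and of 100 genes changed by 3 100% were recovered, with 11 false calls. In simulated values with 1 list shifted by 1 on the log2 scale, camera called that list and 0 of the others. The simulation drew genes independently, which real libraries do not do. It also gave both groups the same spread, while the median SD over genes on the log2 scale was 0.134 in controls and 0.223 in PGC;Ras;APC FF. The shares recovered may therefore overstate what the real comparison can find.

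The alternatives set beforehand were pseudocounts of 0.1 and 5, no filter on low values, a mean FPKM of at least 5, median-of-ratios scaling, quantile normalization, a library total without the 50 most abundant genes, eBayes without trend, eBayes with trend and robust, array weights, a log2 change of at least 1, the other list tests, and leaving out each replicate. Chosen after seeing the data were an adjusted p under 0.1, the estimated correlation together with leaving out replicate 6 or, for 4 lists, with no filter, and leaving out replicate 6 while keeping the genes that passed the filter over all libraries. Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for the depth estimate and the plots.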

Results

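The transcriptome of the stomach corpus was measured by RNA sequencing in 3 control mice (Ras;APC FF) and 3 PGC;Ras;APC FF mice, each library from 1 mouse. The series' title names gastric cancer induced by successive oncogenic activation in the corpus, and the comparison asks which genes differ in the corpus when the PGC component is added to Ras;APC FF. Between 11465 and 12407 genes reached 1 FPKM per library. Relative depth, estimated from short RNAs, lay between 0.742 and 1, and absolute depth is unknown.

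A few digestive genes held much of each library. Pgc (pepsinogen C, a chief cell zymogen), Clps (colipase) and Pla2g1b (a secreted phospholipase, chosen after its values were seen) together took 48.1%, 43.9% and 34.9% of summed FPKM in control replicates 1 to 3. They took 32.7% and 31.7% in PGC;Ras;APC FF replicates 4 and 5, and 6.36% in replicate 6. The median log2 change of all tested genes was 0.26 on the FPKM scale, against -0.0071 after median-of-ratios scaling. How far the share of these 3 genes accounts for that shift was not tested. Replicates 3 and 4 had close shares, while the median FPKM of tested genes was 6.84 in replicate 3 and 7.94 in replicate 4. Replicate 6 stood apart: across genes, its log2 values correlated with the controls at r = 0.904 to 0.909, while replicate 4 did so at 0.965 to 0.974 and replicate 5 at 0.969 to 0.981. Genes are not independent replicates, so no p is given for these r. The Y-linked genes Ddx3y (6.09 FPKM) and Eif2s3y (13.15 FPKM), chosen after their values were seen, were read in control replicate 3, where Xist was at 0. In the other libraries Xist lay between 3.58 and 6.19 FPKM and Eif2s3y was at 0. By these genes replicate 3 reads as male and the others as female. Sex was therefore not balanced between the groups, and the model, with genotype as its 1 term, does not account for it. Leaving out replicate 3 leaves only libraries that read as female. That fit called 0 genes, as did the fits without replicate 1 or 2, so it cannot separate sex from the loss of a control.

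**Figure D1:**
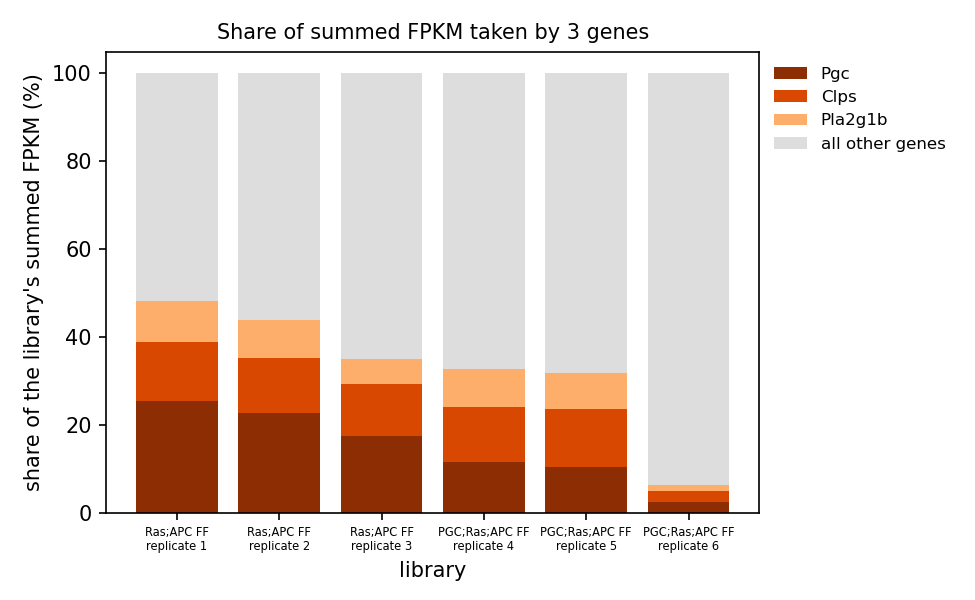
Share of each library's summed FPKM (%, stacked bars from 0) taken by Pgc, Clps, Pla2g1b and all other genes, for the 3 Ras;APC FF and 3 PGC;Ras;APC FF libraries. The 3 named genes took 34.9% to 48.1% in controls and 6.36% in replicate 6.

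Inhibitors of Wnt signalling that are themselves Wnt target genes were among the largest rises in PGC;Ras;APC FF corpus. Notum, a secreted Wnt deacylase (chromosome 11, 120653788 to 120661175, minus strand), had 0.19 ± 0.046 FPKM in controls and 111 ± 98.1 in PGC;Ras;APC FF (SD, n = 3 each), with 83.6, 29.6 and 219.9 in replicates 4 to 6, a rise of 6.12 ± 0.60 (SE) on the log2 scale with a limma adjusted p of 0.0119. Wif1, which binds Wnt ligands (chromosome 10, 121033960 to 121100650, plus strand), went from 0.573 ± 0.191 to 63.3 ± 36.2 FPKM (log2 change 5.14 ± 0.46, limma adjusted p = 0.0103). Bpifb5, of the BPI fold family of secreted proteins (chromosome 2, 154223742 to 154240902, plus strand), was listed at 0 in all 3 controls and at 118, 43.4 and 434 FPKM in replicates 4, 5 and 6. Pla2g2a, a secreted phospholipase gene annotated as a polymorphic pseudogene (chromosome 4, 138831857 to 138835186, plus strand), was likewise listed at 0 in the controls and at 37.5, 14.2 and 109.1 FPKM in replicates 4 to 6. Their limma adjusted p were 0.0119 and 0.0246.

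In all, 13 genes rose and 5 fell of 11857 tested at the limma adjusted threshold of 0.05, and 4196 had an unadjusted p under 0.05. Besides those above, the rises of largest size were Alox15, an arachidonate lipoxygenase (0.237 ± 0.0961 to 31.0 ± 25.6 FPKM, log2 change 4.33, with 25.5, 8.64 and 58.96 FPKM in replicates 4 to 6), and Nccrp1 (0.503 ± 0.198 to 14.9 ± 7.15, log2 change 3.32). They were followed by Crym, a thyroid hormone binding protein (0.2 ± 0.10 to 12.4 ± 7.40, log2 change 3.30) and Lect2 (0.0933 ± 0.0850 to 8.92 ± 4.23, log2 change 3.07), with SD and n = 3 for each mean. The remaining 5 rises, named after their values were seen, were Mt3, Apoc2, Ly6k, Hsd11b2 and Cwh43, with log2 changes of 2.57, 2.31, 1.60, 1.41 and 1.39. The largest fall was in Cfd, the adipocyte-secreted complement factor D (chromosome 10, 79890853 to 79892655, plus strand), from 15.2 ± 2.72 to 0.717 ± 0.530 FPKM (log2 change -3.27 ± 0.25, limma adjusted p = 0.00908). Adipoq, which encodes the adipocyte hormone adiponectin (chromosome 16, 23146536 to 23158028, plus strand), fell from 3.78 ± 1.08 to 0.1 ± 0.13 FPKM. Adcyap1r1, the receptor of the neuropeptide PACAP (chromosome 6, 55451978 to 55501451, plus strand), fell from 5.87 ± 0.313 to 0.647 ± 0.0757 FPKM with the lowest adjusted p of the comparison (limma, 0.00231). Hspb6, a small heat shock protein of muscle, fell from 30.8 ± 3.73 to 11.3 ± 0.913 FPKM, and Pi16 from 7.46 ± 0.792 to 2.82 ± 0.275. Among the 18 genes, every PGC;Ras;APC FF library lay on 1 side of every control library. For genes below 1 FPKM in all controls, such as Notum, Wif1, Bpifb5 and Pla2g2a, the filter itself required this. The naming rule required it too, so it adds no evidence for those genes.

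**Figure D2:**
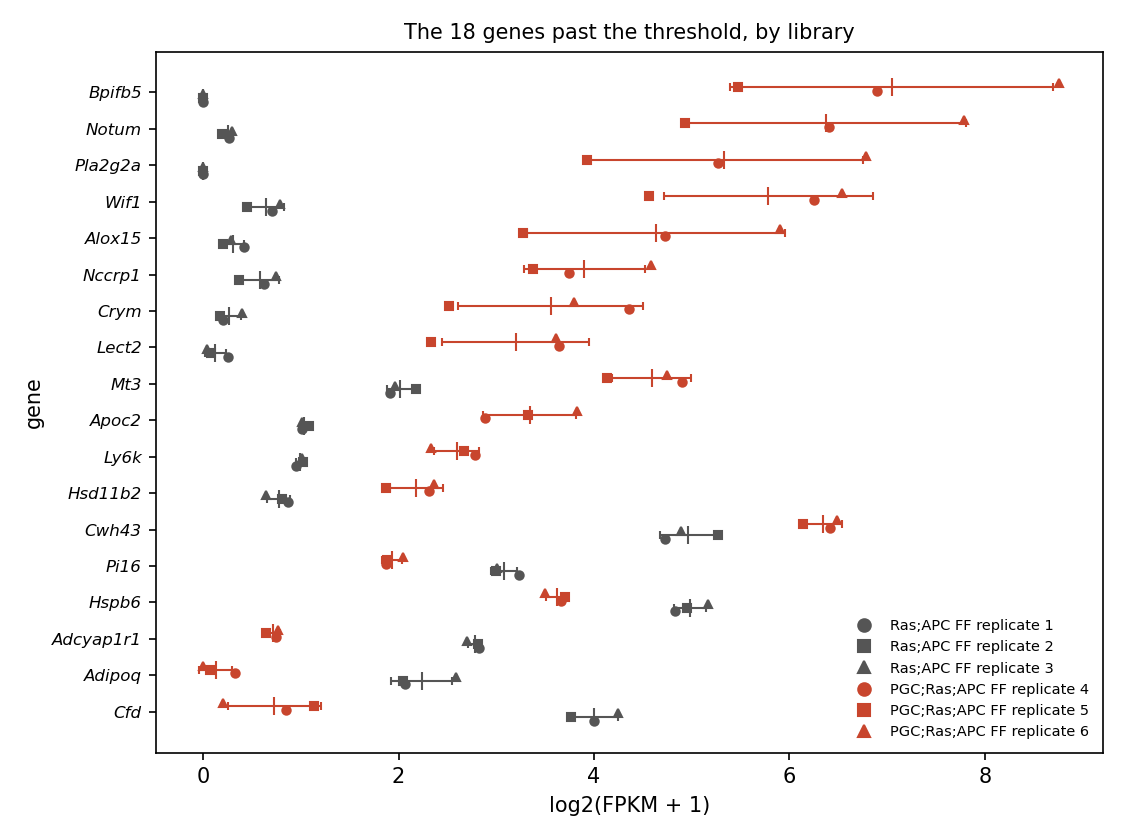
log2(FPKM + 1) of the 18 genes past the threshold in each of the 6 libraries; points are libraries, bars are mean ± SD of the 3 libraries of a group. The 13 genes that rose have every PGC;Ras;APC FF point above every control point and the 5 that fell the reverse. For genes below 1 FPKM in all controls the filter required this separation.

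The number of genes called depended on single libraries. Leaving out any 1 control left 0 calls, although 2270, 2516 and 3056 genes still had an unadjusted p under 0.05 by limma without replicates 1, 2 and 3. Leaving out replicate 6 gave 832 genes higher and 106 lower of 11600, and leaving out replicate 5 gave 413 and 45. Without replicate 4 there were 2 and 3. A setting chosen after seeing the data left out replicate 6 but kept the genes that passed the filter over all 6 libraries. There 962 rose and 114 fell, and all 18 genes were among them. The 18 were chosen on these same libraries together with replicate 6, so finding them again is no independent check. The split between rises and falls moved with scaling, from 72.2% rises on the FPKM scale to 47.4% after median-of-ratios scaling, 43.5% after quantile normalization and 54.5% with a total without the 50 most abundant genes.

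Of Pgc, Hras, Nras and Apc, genes looked at for the genotype labels, none passed the threshold. Pgc was at 168350 ± 27006 FPKM in controls and at 60757 ± 38953 in PGC;Ras;APC FF (SD, n = 3 each, log2 change -1.80 ± 0.84, limma adjusted p = 0.162), with 87455, 78757 and 16059 FPKM in replicates 4 to 6. Without replicate 6 its log2 change was -1.01 (limma adjusted p = 0.146). Hras was at 22.5 ± 2.95 and 29.0 ± 2.23 FPKM. Nras was at 7.58 ± 0.534 and 11.9 ± 2.83 FPKM and Apc at 2.39 ± 0.317 and 3.07 ± 0.858. Gene-level FPKM do not separate altered from unaltered alleles, so these values do not check the genotypes.

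Wnt/beta-catenin target genes stood higher as a group. All 12 tested members had a positive log2 change (median 2.22), 2 rose with adjustment over all genes (Notum and Wif1), 10 did not pass, and 12 rose adjusted over the list alone. In every one of the 12, each PGC;Ras;APC FF library exceeded each control library, which the filter required for Notum and Wif1. Members that did not pass over all genes, chosen after their values were seen, included Nkd1, at 6.26 ± 0.508 and 54.0 ± 45.9 FPKM, Sp5, at 1.51 ± 0.325 and 21.4 ± 18.2, and Axin2, a negative feedback gene of the pathway, at 1.10 ± 0.146 and 14.0 ± 10.7, each with a limma adjusted p of 0.085. Replicate 6 was the highest library for all 3, at 104.7, 41.5 and 25.4 FPKM. The list passed camera (adjusted p = 5.26e-06), with an adjusted p = 0.533 with an estimated correlation. Its level above the control mean was 2.46, 1.45 and 3.34 in replicates 4, 5 and 6, against a control SD of 0.085. Without replicate 6 the median was 1.34 over 10 members (camera adjusted p = 9.5e-05). Notum and Wif1 no longer passed the filter there, so part of the drop in the median came from the change of genes. With the filter over all libraries, a setting chosen after seeing the data, their log2 changes without replicate 6 were 5.42 and 4.76 (limma adjusted p = 0.00119 and 0.00368). Both passed that filter only with replicate 6 counted, so this is no independent check.

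Genes that report RAS-ERK output and cell division were also higher as groups, with 0 members past the threshold over all genes when all 6 libraries were used. Of 17 tested RAS-ERK output genes 0 rose or fell over all genes, and 10 rose adjusted over the list alone. Such counts stand beside 4196 of all 11857 tested genes with an unadjusted limma p under 0.05. The median log2 change was 0.84 (camera adjusted p = 0.0024, and adjusted p = 0.533 with an estimated correlation). Leaving out replicate 6, 7 of 17 rose over all genes (median 0.50, camera adjusted p = 0.000965). Phlda1 was at 50.9 ± 9.03 FPKM in controls and 116.3 ± 41.0 in PGC;Ras;APC FF, and Ier3 at 13.5 ± 2.56 and 38.2 ± 18.6. For proliferation, all 28 tested genes had a positive log2 change (median 0.82) and 28 rose adjusted over the list alone, with 0 over all genes (camera adjusted p = 3.1e-07, and adjusted p = 0.533 with an estimated correlation). With replicate 6 left out, 11 of 27 rose over all genes (median 0.62, camera adjusted p = 1.72e-07). The replication clamp gene Pcna was at 39.6 ± 1.04 and 62.7 ± 11.8 FPKM, and the mitotic ubiquitin-conjugating enzyme gene Ube2c at 18.2 ± 2.88 and 40.4 ± 16.5. Immediate early genes, with Jund at 86.3 ± 23.3 and 106.8 ± 31.1 FPKM and Junb at 65.8 ± 8.37 and 107.9 ± 39.6, did not pass (0 of 9 members, camera adjusted p = 0.445).

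**Figure D3:**
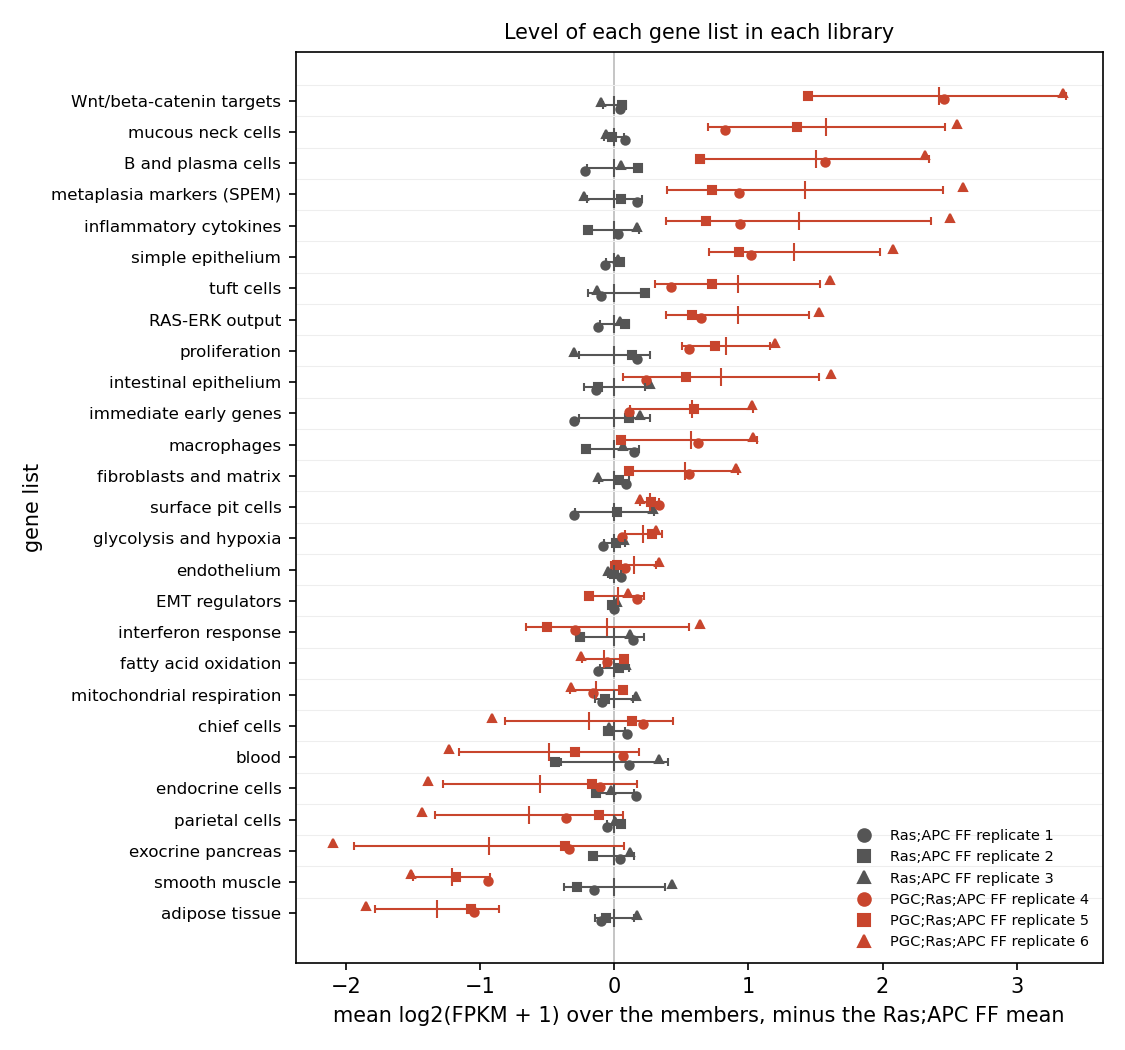
Mean log2(FPKM + 1) over the tested members of each of 27 gene lists, minus the mean of the 3 Ras;APC FF libraries, per library; bars are mean ± SD of the 3 libraries of a group. The Wnt/beta-catenin target list lay 1.45 to 3.34 above the control mean in the PGC;Ras;APC FF libraries and the smooth muscle list fell by 0.95 to 1.52 below it.

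Parietal cell genes were lower as a list (14 of 15 with a negative log2 change, median -0.70, camera adjusted p = 2.21e-10, adjusted p = 0.533 with an estimated correlation), and 0 of 15 passed over all genes or adjusted over the list alone. The proton pump genes Atp4b and Atp4a were at 4379 ± 281 and 2681 ± 287 FPKM in controls and 2568 ± 1637 and 1517 ± 988 in PGC;Ras;APC FF. Replicate 6 held most of this: the list level was -0.36 and -0.12 in replicates 4 and 5 and -1.43 in replicate 6, and the median without replicate 6 was -0.27 (camera adjusted p = 5.53e-08). Chief cell genes passed camera on the lower side (0 of 9 members over all genes, 1 higher adjusted over the list alone, median -0.16, adjusted p = 0.0357, adjusted p = 0.533 with an estimated correlation). Without replicate 6 that call was lost and the median was 0.27 (camera adjusted p = 0.924), and it was lost without replicate 1 too (0.0785). Besides Pgc, Chia1, an acidic chitinase, was at 10297 ± 3800 and 10749 ± 6614 FPKM. Endocrine cell genes were lower in the same way (0 of 9 passed, median -0.52, camera adjusted p = 2.63e-07, adjusted p = 0.533 with an estimated correlation). Ghrelin (Ghrl) was at 2426, 2437 and 722.6 FPKM in replicates 4 to 6 against 2723 ± 425 in controls. Somatostatin (Sst) was at 550.5, 545.2 and 120.4 FPKM against 552 ± 72.7. Their median without replicate 6 was -0.12 (camera adjusted p = 0.00105).

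Mucous neck, tuft and simple epithelial genes stood higher. All 7 mucous neck cell genes had a positive log2 change (median 1.22), and 0 rose over all genes and 6 adjusted over the list alone. The list passed camera (adjusted p = 0.0285, adjusted p = 0.533 with an estimated correlation), but not without replicate 3 or without replicate 5 (camera adjusted p = 0.057 and 0.0521). The trefoil peptide gene Tff2 was at 2304 ± 628 and 6058 ± 4200 FPKM (3567, 3699 and 10906 in replicates 4 to 6), and Agr2, a disulfide isomerase of mucin folding, at 442 ± 47.1 and 1144 ± 421. Among 8 tuft cell genes 0 rose over all genes and 6 adjusted over the list alone (median 0.96). The list passed camera (adjusted p = 0.0285, adjusted p = 0.533 with an estimated correlation), but not without replicate 3 (camera adjusted p = 0.0857), and its median was 0.57 without replicate 6. Among its members were Avil, at 50.1 ± 6.20 and 98.4 ± 30.9 FPKM, and Ptgs1, at 4.78 ± 0.535 and 6.20 ± 1.36. Of 10 simple epithelium genes 0 rose over all genes and 8 adjusted over the list alone (median 0.83, camera adjusted p = 0.00273, adjusted p = 0.533 with an estimated correlation). The median was 0.51 after median-of-ratios scaling and 0.38 after quantile normalization. The keratin genes Krt19 and Krt8 were at 1041 ± 96.4 and 1017 ± 120 FPKM in controls and at 2049 ± 419 and 1787 ± 288 in PGC;Ras;APC FF. Markers of spasmolytic polypeptide-expressing metaplasia (SPEM), a mucous metaplasia of the corpus, missed the threshold (camera adjusted p = 0.0691, adjusted p = 0.703 with an estimated correlation), with 0 of 12 past it over all genes and 7 higher adjusted over the list alone. Clu was at 659 ± 185 and 4239 ± 3739 FPKM (2381, 1793 and 8542 in replicates 4 to 6) and Muc1 at 381 ± 44.0 and 607 ± 176. After median-of-ratios scaling this list passed (camera adjusted p = 0.00228), as it did without replicate 1, 4, 5 or 6 (0.0222 to 0.0295), but with an estimated correlation the adjusted p without replicate 6 was 0.424. Surface pit cell genes did not pass (0 of 12 over all genes, 1 higher adjusted over the list alone, camera adjusted p = 0.276). Tff1 was at 49169 ± 17778 and 58044 ± 3596 FPKM and Gkn2 at 33764 ± 13641 and 29778 ± 2321. The median of this list was 0.12, while camera placed it below the other genes. Intestinal epithelium genes did not pass either (0 of 6 over all genes, 2 higher adjusted over the list alone, camera adjusted p = 0.679), with Spink4 at 96.1 ± 23.0 and 96.9 ± 60.3 FPKM and Vil1 at 11.2 ± 1.67 and 33.3 ± 23.3 (20.6, 19.1 and 60.2 in replicates 4 to 6).

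Genes of the muscle wall and of fat were lower. All 11 smooth muscle genes had a negative log2 change (median -1.25), and in each of them every PGC;Ras;APC FF library lay below every control library. None passed over all genes, 11 fell adjusted over the list alone, and the list had the lowest camera p (adjusted p = 3.14e-22, adjusted p = 0.369 with an estimated correlation). When replicate 6 was left out, 9 of 11 fell over all genes (median -1.10, camera adjusted p = 9.06e-19). The actin genes Actg2 and Acta2 were at 732 ± 293 and 579 ± 83.9 FPKM in controls and at 266 ± 64.6 and 283 ± 65.6 in PGC;Ras;APC FF. Of 6 tested adipose genes 2 fell over all genes (Cfd and Adipoq), 4 did not pass, and 3 fell adjusted over the list alone (median -0.83, camera adjusted p = 2.21e-10, adjusted p = 0.369 with an estimated correlation). Without replicate 6 the adipose median was -0.47 (camera adjusted p = 6.21e-09). Fibroblast and matrix genes (0 of 17 past the threshold, median 0.46, camera adjusted p = 0.074), endothelial genes (0 of 10, median 0.035, 0.074) and regulators of the epithelial-mesenchymal transition (0 of 5 over all genes, 1 higher and 1 lower adjusted over the list alone, median -0.077, 0.096) did not pass camera. Dcn was at 98.2 ± 12.04 and 125.5 ± 43.1 FPKM and Sparc at 73.6 ± 3.88 and 103.2 ± 23.7. Pecam1 was at 13.2 ± 1.82 and 12.6 ± 0.465 FPKM and Egfl7 at 8.18 ± 0.680 and 9.59 ± 1.99. Vim was at 52.7 ± 8.01 and 49.96 ± 7.91 FPKM and Snai1 at 3.30 ± 0.701 and 5.14 ± 1.58. After median-of-ratios scaling the fibroblast list was higher and the endothelial list lower (camera adjusted p = 0.037 each). Leaving out replicate 1 or 5 also gave a call for the fibroblast list (0.0243 and 0.0015), and leaving out replicate 3 or 6 for the endothelial list (0.0219 and 0.0151). With an estimated correlation the adjusted p of the fibroblast and endothelial lists were 0.724 and 0.533, and 0.852 and 0.362 without replicate 6.

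Immune gene lists gave no call that held throughout. Interferon response genes were called lower (0 of 15 past the threshold, camera adjusted p = 0.00154, adjusted p = 0.533 with an estimated correlation) although their median was -0.044. Without replicate 6 the median was -0.53 (camera adjusted p = 1.06e-10), and 3 of 14 members fell over all genes and 7 adjusted over the list alone. The list level was -0.30 and -0.50 in replicates 4 and 5 and 0.64 in replicate 6. Without replicate 5 the list did not pass (camera adjusted p = 0.126). Irf7 was at 25.7 ± 5.03 and 22.7 ± 12.5 FPKM and Bst2 at 27.8 ± 5.89 and 31.8 ± 17.5. Inflammatory cytokine genes (0 of 5 over all genes, 4 higher adjusted over the list alone, median 1.27, camera adjusted p = 0.0753), macrophage genes (0 of 9, 1 higher adjusted over the list alone, 0.321) and B and plasma cell genes (0 of 3, 3 higher adjusted over the list alone, median 1.36, 0.05) did not pass. The B and plasma cell list lay at the threshold itself, and passed without replicate 2, 5 or 6 (camera adjusted p = 0.0423, 0.00125 and 0.0436). The macrophage list passed without replicate 5 (0.00799). With an estimated correlation the adjusted p of the B and plasma cell and macrophage lists were 0.533 and 0.786, and 0.46 and 0.971 without replicate 6. Il33 was at 27.5 ± 9.93 and 67.4 ± 27.6 FPKM and Il1b at 0.89 ± 0.34 and 6.02 ± 5.42 (4.18, 1.77 and 12.12 in replicates 4 to 6). The complement genes C1qa and C1qb were at 33.4 ± 5.28 and 32.3 ± 6.87 FPKM in controls and at 68.2 ± 34.6 and 63.7 ± 30.6 in replicates 4 to 6. The antibody joining chain gene Jchain was at 23.7 ± 5.85 and 97.9 ± 55.1 FPKM and Mzb1 at 1.06 ± 0.346 and 5.23 ± 4.40 (3.97, 1.59 and 10.12 in replicates 4 to 6).

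Among metabolic lists, mitochondrial respiration (0 of 19 past the threshold, median -0.14) and fatty acid oxidation (0 of 12, median -0.058) were called lower relative to other genes (camera adjusted p = 3.91e-07 and 0.00154, adjusted p = 0.533 with an estimated correlation for both). Atp5b was at 945 ± 22.0 and 870 ± 165 FPKM and Cox4i1 at 681 ± 181 and 604 ± 71.4. Hadhb was at 92.7 ± 14.0 and 84.1 ± 3.49 FPKM and Echs1 at 95.1 ± 8.62 and 81.1 ± 11.2. Without replicate 6 the medians were -0.039 and 0.0019 (camera adjusted p = 0.000926 and 0.0347, both on the lower side). After median-of-ratios scaling, which takes out most of the shift of 0.26 in the median of all genes, the medians were -0.45 and -0.37 (camera adjusted p = 3.05e-05 and 0.00228). Glycolysis and hypoxia genes did not pass (0 of 17, median 0.24, camera adjusted p = 0.623), with Gapdh at 1080 ± 48.2 and 1397 ± 163 FPKM and Aldoa at 633 ± 40.8 and 759 ± 79.6. For glycolysis the median was positive while camera placed the list lower.

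Lists of neighbouring tissues were read in the same libraries. Exocrine pancreas genes (0 of 6 over all genes, 1 lower adjusted over the list alone, median -0.59) and blood genes (0 of 4, median -0.50) were called lower (camera adjusted p = 0.000383 and 0.00221, adjusted p = 0.533 with an estimated correlation for both). Both calls were lost without replicate 6 (medians 0.15 and -0.064, camera adjusted p = 0.188 and 0.105). Clps was at 97711 ± 4787 and 71000 ± 46861 FPKM (95333, 100690 and 16978 in replicates 4 to 6) and Try4 at 163 ± 44.7 and 149 ± 94.6. The member lower adjusted over the list alone was Amy2a5, named after its values were seen, at 95.7 ± 86.4 and 6.45 ± 4.62. Pancreas list members left out by the filter lay at or below 1.18 FPKM in every library, with Prss2, Cpa1 and Ctrl at or below 0.09. The pancreas call can therefore not be read as a change in pancreas tissue. Hba-a1 was at 135 ± 28.1 and 119 ± 28.9 FPKM and Hbb-bs at 148 ± 62.5 and 88.2 ± 37.0. The lists of neutrophils, T and NK cells, squamous forestomach, and antral and duodenal genes had fewer than 3 tested members and were not tested as lists in the main setting. Without a filter, the squamous forestomach list (13 genes, median 0.12) was called higher (camera adjusted p = 0.046, and adjusted p = 0.648 with an estimated correlation, a test chosen after seeing the data), and the others did not pass (0.26 to 0.988). Of the immune lists the tested members were Mmp9, at 0.36 ± 0.010 and 8.66 ± 5.71 FPKM, Cd3g, at 0.79 ± 0.22 and 2.56 ± 1.73, and Cd4, at 1.22 ± 0.0153 and 1.67 ± 0.544. Of the tissue lists they were Sprr1a, at 74.1 ± 41.1 and 207 ± 108, Krt13, at 0.41 ± 0.37 and 3.33 ± 1.18, and Gata4, at 71.4 ± 4.35 and 83.0 ± 17.2. None of them passed over all genes. Adjusted over the list alone, Mmp9, Cd3g, Krt13 and Sprr1a passed as higher, and Cd4 and Gata4 did not pass. With 1 or 2 tested members per list this adjustment changes little, and 4196 of 11857 genes had an unadjusted limma p under 0.05. These passes therefore do not stand for the cell types or tissues of the lists.

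Counts of members past the threshold over all genes depended on replicate 6 in further lists. Without it, 6 of 10 Wnt/beta-catenin target genes, 2 of 7 mucous neck, 3 of 8 tuft, 3 of 9 simple epithelium, 4 of 11 SPEM and 2 of 3 B and plasma cell genes rose over all genes. So did 1 gene each of the chief, surface pit, intestinal epithelium and glycolysis lists, and 1 gene each of the endocrine and exocrine pancreas lists fell. Without replicate 6 the filter dropped Notum and Wif1 of the Wnt list, Cldn7 of simple epithelium and Muc4 of SPEM from these counts. With the filter over all libraries, a setting chosen after seeing the data, these genes rose (limma adjusted p = 0.00119, 0.00368, 0.0218 and 0.026). They passed that filter only with replicate 6 counted.

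Of the 27 lists tested, 6 were called higher and 10 lower with the preset correlation. In splits of the libraries that mix the genotypes, examined after these results were seen, the same test called 8 to 19 lists. With the correlation estimated per list, 0 were called, the lowest adjusted p being 0.369 (0.362 without replicate 6, again with 0 called), and fry called 0, the lowest adjusted p being 0.106.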

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

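The settings below include 4 chosen after seeing the data: the adjusted p under 0.1, leaving out replicate 6 with the filter over all libraries, and the estimated correlation with replicate 6 left out or, for 4 lists, without a filter; the others were set before the data were examined. Against 13 rises and 5 falls, a pseudocount of 0.1 gave 29 rises, a pseudocount of 5 gave 2 and 3, no filter gave 3 rises, a mean FPKM of at least 5 gave 7 and 2, robust eBayes gave 7 rises and array weights, whose estimate stopped before it converged, gave 3523 and 369. Falls numbered 10 after median-of-ratios scaling, 13 after quantile normalization and 10 with a total without the 50 most abundant genes. An adjusted p under 0.1 gave 2019 and 226, since many genes shared an adjusted p of 0.085. Leaving out 1 replicate gave 0 to 832 rises and 0 to 106 falls, and leaving out replicate 6 with the filter over all libraries gave 962 and 114; fewer libraries change both the spread and the genes tested, and no further cause was tested. All 18 genes kept their sign wherever they were tested. eBayes without trend and a log2 change of at least 1 left 13 and 5.

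Of the 16 lists called with camera, 10 kept the call and its direction in all 16 other camera settings with the preset correlation: parietal, endocrine, Wnt/beta-catenin targets, RAS-ERK output, proliferation, smooth muscle, simple epithelium, adipose tissue, mitochondrial respiration and fatty acid oxidation. After median-of-ratios scaling their medians were -0.91, -0.78, 1.96, 0.61, 0.54, -1.56, 0.51, -1.14, -0.45 and -0.37 in that order. Without a filter 31 lists were tested in place of 27, of which 10 were called higher. Of the 4 lists tested there alone, squamous forestomach was called (median 0.12, camera adjusted p = 0.046, and 0.648 with an estimated correlation). At a mean FPKM of at least 5, 23 were tested. Of 27 lists, those called higher numbered 10 in place of 6 after median-of-ratios scaling, after quantile normalization and with a total without the 50 most abundant genes. The estimated correlation, fry, and the estimated correlation with replicate 6 left out called 0 lists higher and 0 lower; the cause was not tested. Leaving out 1 replicate gave 4 to 9 lists higher and 8 to 11 lower.

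For single lists the value given is the median log2 change, and why a call came or went was not tested. The chief cell call was lost at -0.16 without a filter, -0.48 after median-of-ratios scaling, -0.53 after quantile normalization, -0.53 with a total without the 50 most abundant genes and 0.24 with array weights. In the last 4 of these settings exocrine pancreas was also lost (-0.88, -0.53, -0.93 and 0.050), as was blood (-0.80, -0.82, -0.85 and 0.055). Array weights ended the calls of mucous neck (0.83) and tuft cells (0.51). Calls were gained for SPEM markers without a filter (1.23), at a mean FPKM of at least 5 (1.06) and under the 3 scalings in that order (0.75, 0.69 and 0.69). Inflammatory cytokines were gained with a pseudocount of 0.1 (1.87), without a filter (1.05) and under the scalings (1.07, 1.05 and 1.04). B and plasma cells were gained with a pseudocount of 0.1 (1.90), under the scalings (1.14, 1.17 and 1.12) and with array weights (1.29). Fibroblasts were gained without a filter (0.46), under the scalings (0.18, 0.19 and 0.14) and with array weights (0.39). Endothelium was gained on the lower side after median-of-ratios scaling (-0.23), quantile normalization (-0.23) and array weights (-0.12), and EMT regulators on the lower side without a filter (-0.077).

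The calls ended by both the estimated correlation and fry had medians of -0.16 (chief), -0.70 (parietal), 1.22 (mucous neck), -0.52 (endocrine), 0.96 (tuft), 2.22 (Wnt), 0.84 (RAS-ERK) and 0.82 (proliferation). The others were at -0.044 (interferon), -1.25 (smooth muscle), 0.83 (simple epithelium), -0.59 (exocrine pancreas), -0.83 (adipose), -0.50 (blood), -0.14 (respiration) and -0.058 (fatty acid oxidation). With an estimated correlation and without replicate 6, these medians were 0.27, -0.27, 0.87, -0.12, 0.57, 1.34, 0.50, 0.62, -0.53, -1.10, 0.57, 0.15, -0.47, -0.064, -0.039 and 0.0019 in that order. Over the 6 fits that leave out 1 replicate, medians ran from -0.43 to 0.27 for chief cells, 0.87 to 1.495 for mucous neck cells, 0.44 to 1.24 for SPEM markers, 0.57 to 1.28 for tuft cells and -0.53 to 0.21 for interferon response. They ran from 0.44 to 0.95 for macrophages, 1.04 to 1.87 for B and plasma cells, 0.36 to 0.63 for fibroblasts, -0.073 to 0.12 for endothelium, -0.9998 to 0.15 for exocrine pancreas and -0.84 to -0.064 for blood.

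None of the single genes whose direction turned was past the threshold in either setting, and why they turned was not tested. The log2 change was -0.018 for Tff1, -0.22 for Bst2, -0.021 for Dcn, -0.093 for Egfl7, -0.12 for Gata4, -0.059 for Aldoa and -0.014 for Jund after median-of-ratios scaling. After quantile normalization it was 0.31 for Gkn2, -0.24 for Bst2, -0.046 for Dcn, -0.10 for Egfl7, -0.17 for Gata4, 0.27 for Clps, -0.093 for Gapdh, -0.22 for Aldoa and -0.044 for Jund. With a total without the 50 most abundant genes it was -0.025 for Apc, -0.071 for Tff1, -0.010 for Ptgs1, -0.27 for Bst2, -0.073 for Dcn, -0.14 for Egfl7, -0.17 for Gata4, -0.0016 for Gapdh, -0.11 for Aldoa and -0.066 for Jund. With array weights it was 0.68 for Chia1, 0.15 for Gkn2, -0.28 for Bst2, 0.24 for Try4 and 0.073 for Hba-a1. Over the 6 fits that leave out 1 replicate the log2 change ran from -0.16 to 0.017 for Pecam1, -0.32 to 0.31 for Bst2, -0.58 to 0.56 for Chia1, -0.34 to 0.20 for Gkn2 and -0.63 to 0.31 for Spink4. It ran from -0.19 to 0.041 for Vim, -0.26 to 0.058 for Cox4i1, -1.28 to 0.0050 for Clps, -0.84 to 0.35 for Try4, -0.36 to 0.0025 for Hba-a1 and -0.27 to 0.0013 for Atp5b. The fits that turned these directions left out replicate 6 for Chia1, Bst2, Clps, Try4, Hba-a1 and Atp5b. They left out replicate 3 for Chia1, Gkn2, Spink4, Vim and Cox4i1, replicate 1 or 2 for Pecam1, replicate 2 for Bst2, replicate 4 for Spink4 and replicate 5 for Vim.

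For lists, the direction given by the test and the sign of the median could part. The median changed its sign while the test kept its direction for chief cells, exocrine pancreas, blood, interferon response, fatty acid oxidation and endothelium, each called in at least 1 of the settings compared. Interferon response went from -0.044 to 0.11 without replicate 1, and fatty acid oxidation from -0.058 to 0.0019 without replicate 6, with a call in both settings. In the lists that follow, the direction given by the test turned, and none was called in either setting. The glycolysis and hypoxia median was 0.24 without a filter and with fry, 0.32 without replicate 4, and 0.15 without replicate 6 with either correlation. The intestinal epithelium median was 0.54 at a mean FPKM of at least 5, and ran from 0.049 to 0.91 over the fits that leave out 1 replicate, turning at 0.049 without replicate 6 with either correlation. For glycolysis that range was 0.15 to 0.32. With array weights the medians were 0.26 for surface pit cells and 0.15 for immediate early genes, and with fry the direction turned for surface pit cells (median 0.12), EMT regulators (-0.077) and endothelium (0.035).

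No paired analysis was possible because the groups share no replicate numbers. The planned count model was not run because the values are FPKM. Absolute depth is unknown, so how far low FPKM can be trusted is not known either.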

Other observations

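The gene families and single genes of this paragraph were chosen after their values were seen, and none of the genes given with values passed the threshold over all genes. Of 7 families looked at, 1 is described, and the other 6, of 3 to 13 tested genes each, had median log2 changes of 0.70 to 3.28. All 74 tested cytosolic ribosomal protein genes had a positive log2 change (median 0.65), and in 64 of them every PGC;Ras;APC FF library lay above every control library, as in 42.7% of all tested genes. After median-of-ratios scaling this held for 48 of the 74, against 17.6% of all tested genes. The median was 0.34 after that scaling, with 73 of 74 positive, and 0.25 after quantile normalization, with 71 positive. Lcn2, a siderophore-binding protein of inflamed epithelium, was at 56.7, 13.5 and 291.2 FPKM in replicates 4, 5 and 6 and at 0.64 to 1.49 in controls. Cym, the gastric protease chymosin, was at 175.3, 39.8 and 1189 FPKM against 0.63 to 4.74 in controls. The tight junction gene Cldn4 was at 19.1, 5.14 and 57.5 FPKM against 0.06 to 0.15, and Cldn7 at 13.6, 4.89 and 91.6 against 0.74 to 0.99. Krt7 was at 89.9, 49.5 and 350.6 FPKM against 6.72 to 8.55, and Stra6, a retinol transporter, at 35.4, 8.67 and 88.2 against 0.01 to 0.05. For Reg3g, an antimicrobial lectin, replicate 6 stood alone at 265.9 FPKM, with 6.90 and 8.27 in replicates 4 and 5 and 0 to 4.31 in controls.

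Of 11857 tested genes, 5066 (42.7%) had every PGC;Ras;APC FF library above every control library and 649 (5.47%) every one below, where chance gives 10% for both sides together. After median-of-ratios scaling these numbers were 2083 and 2074.

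The tests given from here on were all chosen after the result they bear on was seen. Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, called as many as 18 genes, and the highest of the others called 0. For gene lists, 4 of the 10 splits called at least the 16 lists of the real one, and the others ranged from 8 to 19. Camera with the preset correlation thus called lists in every split, also in those that mix the genotypes. A list call by that test alone does not set the genotypes apart from other groupings of these libraries. With 10 splits no share under 0.05 can be had, so neither count decides on chance.

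Smooth muscle genes were lower in all 3 PGC;Ras;APC FF libraries, along with Cfd, Adipoq and Hspb6. Dilution by an expanded epithelium would lower other non-epithelial genes alike, but the endothelial list level exceeded the smooth muscle one by at least 1.03 in every PGC;Ras;APC FF library (control SD 0.416), which argues against it as the whole cause. A total set by few genes would move all genes of a library alike, but in every PGC;Ras;APC FF library the smooth muscle list level minus the median of all tested genes, relative to controls, was -1.12 or lower (control SD 0.364), which argues against it as the whole cause. The 11 smooth muscle genes were lower by like amounts (SD between genes 0.212 around a median of -1.25), as less muscle wall in the collected tissue would give. A difference in dissection, or a mucosa thickened together with its own vessels over the same muscle, may therefore account for the lower muscle genes. Fat genes were not part of that test, and their log2 changes ran from -3.27 (Cfd) to -0.10 (Cidec). Among controls the smooth muscle list level was highest in replicate 3 (0.43, against -0.15 and -0.28 in replicates 1 and 2). Without replicate 3 the smooth muscle median was -0.97. A change in the muscle itself linked to the genotype stays open and was not tested.

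Replicate 6 lay farther from the controls than replicates 4 and 5 did for 25 of the 27 lists. A total set by few genes would move all lists alike, but for 19 of the 27 the level relative to the median of all tested genes differed between replicate 6 and the mean of replicates 4 and 5 by more than 0.5 and by more than 2 control SDs. It was higher in replicate 6 for 10 of them and lower for 9, which argues against such a total as the whole cause. Dilution of the gastric epithelium by other cells would lower pit genes with parietal genes, but the pit minus parietal level was 1.09 higher in replicate 6 (control SD 0.269). Antral or duodenal mucosa in the tissue stays open, since 3 of 7 genes of that list were highest in replicate 6. Among these genes, named after their values were seen, Pdx1 was at 3.42 FPKM there against 0.26 to 0.97 in the other libraries and Onecut2 at 5.96 against 0.02 to 0.56. Gastrin (Gast), at 0.07 FPKM in replicate 6, and Nkx6-3, at 0.16, were highest in control replicate 3, at 4.41 and 1.90. A more extensive lesion in that mouse may be a candidate explanation as well. The labels give no histology, and it was not tested.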
